A study of Drosophila melanogaster with 3 samples.

How the data were processed

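The data were chromatin immunoprecipitation sequencing (ChIP-seq) of Mirror, a homeodomain transcription factor of the Iroquois family, in whole Drosophila melanogaster embryos. Per the labels, the embryos were of mixed sex and aged 4 to 20 h, and came from a transgenic line that carries mirr fused to GFP. Chromatin was sonicated to a size range of 200 to 800 bp. The 3 samples formed 1 group and carried biological replicate numbers 1, 2 and 3, so the design held no comparison between groups. The free-text description of each sample names an input control, whereas the title, the assay field and the antibody field name transcription factor ChIP; the lists were read as ChIP peak lists because the deposited file descriptions name a control alignment beside the ChIP alignment of each list. The age field holds a garbled number, and the age was taken from the sample source field.

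Per the file headers and the deposited descriptions, the authors aligned reads to dm6, called peaks in each replicate against the same control alignment, and called peaks again on all 3 alignments together. An irreproducible discovery rate (IDR) procedure, which keeps peaks whose ranks recur between replicates, was then applied to these lists. The aligner, the caller, the IDR threshold and read numbers were not given in the sources used here. Sequencing depth is therefore unknown, no counting interval could be given, and a difference between replicate lists may partly follow depth. Each relaxed list, called without an IDR threshold, held exactly 30000 regions in every replicate and in the pooled call, so its length carries no information. The value of each peak is the signal deposited by the authors in the signal column of the peak lists, without a stated scale; it was used to rank peaks within a list and, in 1 test of the closing section, halved and set against the lowest IDR signal. The 6201 IDR peaks were the 6201 pooled regions with the highest signal. Presence in this list therefore does not show that a given peak recurred in each replicate. Signal tracks and alignments were not used here.

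Peaks were placed on the Ensembl 115 gene annotation of BDGP6.54, whose chromosome arms are those of dm6, and on the release 6 reference sequence. Only protein-coding genes on arms 2L, 2R, 3L, 3R, X and 4 were used, which gave 13945 genes with 19607 transcription start sites (TSSs). A summit was assigned to the first matching category of TSS within 500 bp, 5' UTR, 3' UTR, coding exon, intron and intergenic. The background for categories and arms was the 22666 pooled regions that overlapped no IDR peak, called relaxed-only regions here. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 6 categories, the 6 arms, 16 sequences or 24 gene lists, at a threshold of 0.05. Sequences were searched on both strands within 100 bp of summits and in windows of the same size centred 1000 bp to each side. The Iroquois sequence was also ranked among all 64 palindromes with a 2-base spacer. A gene counted as bound when an IDR summit lay within 1000 bp of one of its TSSs. Each list was also set against 10000 random lists of the same size matched on decile of locus length, with a two-sided p that cannot go below 0.0002 and Benjamini-Hochberg adjustment, because developmental genes have long loci. Replicate agreement was compared with 100 shuffles of the replicate peaks within arms, and ranks were compared by permutation tests with 100000 resamples. The number of summits at the Iroquois complex was compared with all windows of the same length at 10-kb steps.

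For the spread between replicates, each statistic was recomputed on the 6201 strongest regions of each replicate list and given as mean ± SD (n = 3). Peaks and genes are not biological replicates: p-values describe these lists and not the variation between embryo collections. The 3 replicate lists share 1 control, so background common to that control is shared as well.

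The gene lists, sequences, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named ara, caup and mirr; the gene with the TSS nearest to each of the 25 strongest peaks; for each list that passed the test, up to 4 bound members with the strongest peaks and up to 2 unbound members in alphabetical order; and genes with a TSS in the 5 windows of 50 kb that held the most summits, of which 1 is not reported here. Alternatives were the overlap rule, the TSS and sequence windows, the background, the assignment of peaks to genes, the 3100 strongest IDR peaks and leaving out each replicate, which gave the mean over the remaining replicate lists and counted as passing only where each of them passed. Keeping 1 summit per merged region was added after the data were seen.

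The calculations were tested on simulated data. A simulated log2 odds ratio of 1.5 among 6000 summits was recovered as 1.51 on average. A sequence planted in 300 of 3000 windows was called, and 0 of the other sequences were. Summit and flank windows were drawn there from the same random bases, so differences in composition between real summits and flanks were not simulated. A raised ribosomal protein list was called in 99 of 100 simulations, with 3 calls of other lists among 2300. All other genes were bound there independently at the same rate. Calls that follow locus length or neighbouring genes were therefore not simulated. Overlap found 69.7% of 5000 simulated peaks as shared, equal to the simulated share. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.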

Results

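Binding of GFP-tagged Mirror was mapped by ChIP-seq in whole embryos aged 4 to 20 h, in 3 biological replicates. Mirror (mirr), Araucan (ara) and Caupolican (caup) are the homeodomain proteins of the Iroquois complex, known for patterning the eye, the wing and the dorsal body wall. The IDR list held 6201 peaks with a median width of 396 bp, which covered 1.98 Mb of the dm6 genome; 52 of them repeated the interval of another peak with a different summit. Their signal ranged from 190.7 to 4323. Sequencing depth was unknown, and the samples held no untreated or untagged group.

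The first question was how far the replicates gave the same peaks. Of the 6201 IDR peaks, 3481 (56.1%) were overlapped by the 6201 strongest regions of each of the 3 replicates, 1949 (31.4%) by those of exactly 2, 739 (11.9%) by those of 1 and 32 (0.516%) by none. The share overlapped per replicate was 81.1% ± 2.90 (SD, n = 3), with 82.3% in replicate 1, 77.7% in replicate 2 and 83.1% in replicate 3. Shuffled replicate peaks overlapped on average 3.21%, 3.09% and 3.05% of IDR peaks, and all 3 shuffled lists overlapped at most 0.0323%. Across the IDR peaks found in both relaxed lists of a pair, Spearman's rho of the ranks was 0.520 for replicates 1 and 2, 0.602 for replicates 1 and 3 and 0.503 for replicates 2 and 3; peaks are not independent replicates. The IDR list was derived from these same lists, so the overlap is not independent evidence for it. The share in all 3 replicates fell to 33.2% with 50% reciprocal overlap and reached 93.8% with the whole relaxed lists. Widths bear on the first value, because an IDR peak much narrower than a replicate region cannot meet the 50% rule. The most common width of its list was held by 53.0% of IDR peaks. In the relaxed lists of replicates 1, 2 and 3 it was held by 91.2%, 94.3% and 95.8% of regions. With summits within 100 bp, a rule without widths, the share was 48.4%.

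The 25 strongest peaks lay near genes of several kinds. Peaks 5 and 8 were nearest to mirr itself. The strongest of all lay 37 bp from a TSS of Ugalt, which encodes a UDP-galactose transporter, on chromosome X at 2703702 to 2704078, with a signal of 4323 and ranks 2, 3 and 3 in replicates 1, 2 and 3. Peak 2 lay 92 bp from a TSS of CG14100, and peak 3 was intergenic, 2910 bp from a TSS of hll, with ranks 11, 2 and 1. Others were nearest to Gapdh2, a glycolytic enzyme gene (peak 9, 154 bp from the TSS), eIF6, a ribosome biogenesis factor gene (peak 10, 102 bp), RpS27 (peak 21, 12 bp), the Hsp90 chaperone gene Hsp83 (peak 22, 111 bp) and mRpL41, a mitochondrial ribosomal protein gene (peak 23, 124 bp). RYBP and ph-p, which encode Polycomb group proteins, were nearest to peaks 14 and 16, at 7569 bp and 483 bp. Peak 18 had the TSS of the transcription factor gene cbt nearest, at 1373 bp, but lay in an intron of ush. The remaining ones were nearest to CG11050, CG9663, CG1888, Pal1, CG9837, CG11309, Art3, Lk6, CenG1A, jp, Cpr and Tlk. Of the 25, 15 lay within 500 bp of a TSS, 6 in introns and 4 in intergenic sequence.

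Promoters held a larger share of IDR summits than of relaxed-only summits. Of the IDR summits, 45.0% lay within 500 bp of a TSS, against 22.2% of relaxed-only summits and 11.5% of the bases of the chromosome arms (log2 odds ratio against relaxed-only regions 1.52, SE 0.04, Fisher's exact test, adjusted p = 2.42e-261). The share in the replicate lists was 44.1% ± 6.28 (SD, n = 3), with 51.0%, 42.4% and 38.8% in replicates 1, 2 and 3. Introns held 39.1% of IDR summits and 48.7% of relaxed-only summits (log2 odds ratio -0.56, SE 0.04, exact test, adjusted p = 1.1e-40), although their share of bases was 39.3%, close to that of the IDR summits. In the replicate lists introns held 35.0%, 40.6% and 42.9% of summits in replicates 1, 2 and 3, above the promoter share in replicate 3, and with a TSS window of 250 bp the promoter share of IDR summits was 37.1%. Intergenic sequence held 12.7% against 23.4% (log2 odds ratio -1.08, SE 0.06, exact test, adjusted p = 6.19e-82), and coding exons 0.468% against 2.76% (log2 odds ratio -2.57, SE 0.27, adjusted p = 1.75e-35). The shares in 5' UTRs, 1.10% against 0.944%, and in 3' UTRs, 1.66% against 2.00%, did not pass the test (exact test, adjusted p = 0.275 and 0.114); in the replicate lists the 3' UTR passed without replicate 2, at a mean log2 odds ratio of -0.48.

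**Figure D1:**
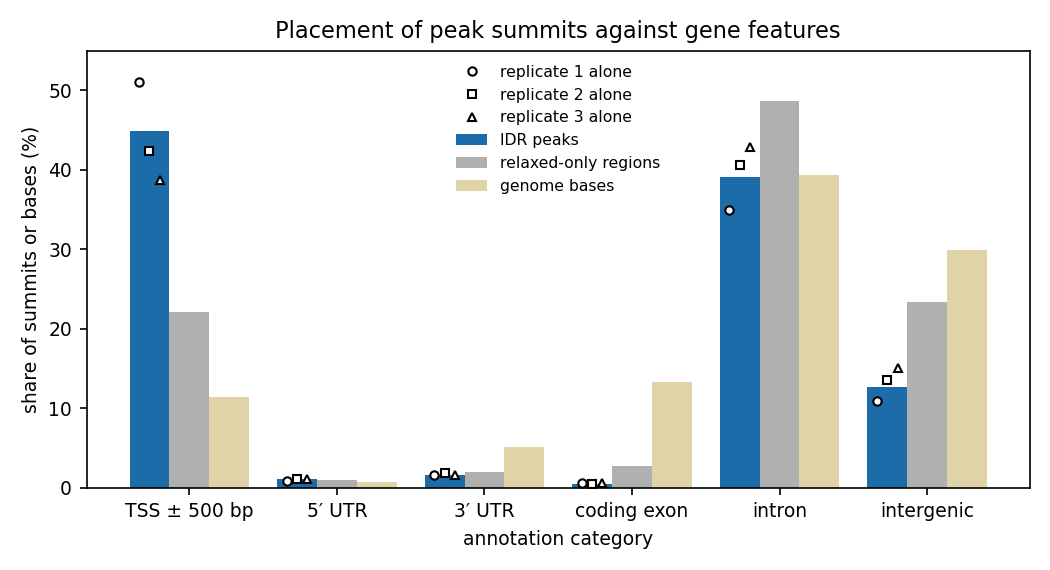
Share (%) of IDR summits, relaxed-only summits and genome bases in each annotation category; the open symbols give the 6201 strongest regions of each replicate. Promoter summits made up 45.0% of the IDR list and 22.2% of the relaxed-only regions.

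The Iroquois binding sequence was more frequent at summits than beside them. ACANNTGT, the palindrome bound by Iroquois proteins in vitro, occurred within 100 bp of 832 summits (13.4%), against 8.33% of flanking windows and 10.2% of relaxed-only summits. The ratio to flanks was 1.61 (log2 odds ratio 0.77, SE 0.07, Fisher's exact test, adjusted p = 5.96e-26), and 1.56 ± 0.0521 in the replicate lists (SD, n = 3). It ranked 3 among the 64 palindromes of this form, after ACGNNCGT with a ratio of 1.81 and GTANNTAC with 1.65, and 3, 5 and 2 in replicates 1, 2 and 3. Among the 24 palindromes of its base composition it ranked 2, after GTANNTAC; the other 23 had ratios from 0.618 to 1.65, with a median of 0.938.

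Sequences of other factors exceeded it. The GATA factor sequence WGATAAG occurred at 20.1% of summits and 7.39% of flanks (ratio 2.72, log2 odds ratio 1.66, SE 0.07, exact test, adjusted p = 1.31e-133). The promoter elements DRE (TATCGATA) and Motif 1 (GGTCACACT) were rarer, at 2.52% and 1.42% of summits, but had ratios of 4.16 and 4.00; among peaks over 1000 bp from a TSS their log2 odds ratios were 0.04 and -0.59 and did not pass the test. The CA repeat (ratio 2.04), the GAGA sequence (1.96), CATATG (1.25), the TALE homeodomain sequence TGACAG (1.23) and CAGCTG (1.21) were also more frequent at summits. Against relaxed-only summits the CA repeat no longer passed the test (log2 odds ratio -0.05), and TGACAG was less frequent at IDR summits (log2 odds ratio -0.35). The TGACAG call was also lost with 250-bp windows (0.097) and for the 3100 strongest peaks (0.27). The TAATTA homeodomain sequence (ratio 0.887), the STAT sequence (0.740) and the TCF sequence (0.580) were less frequent at summits than in flanks. Against relaxed-only summits the STAT call was lost (log2 odds ratio 0.037). The TCF call was lost with 50-bp windows (log2 odds ratio -0.45), among peaks over 1000 bp from a TSS (-0.59) and without replicate 1 (-0.45) or replicate 3 (-0.47). The homeodomain call was lost for the 3100 strongest peaks (-0.072) and without replicate 2 (-0.13) or replicate 3 (-0.21), and its sign changed against relaxed-only summits (0.14) and with 250-bp windows (0.015). The CAGCTG call was lost among peaks over 1000 bp from a TSS (0.066). The Zelda (0.753), CACCTG (0.945), Su(H) (0.904) and Grainy head (1.5) sequences did not pass the test.

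**Figure D2:**
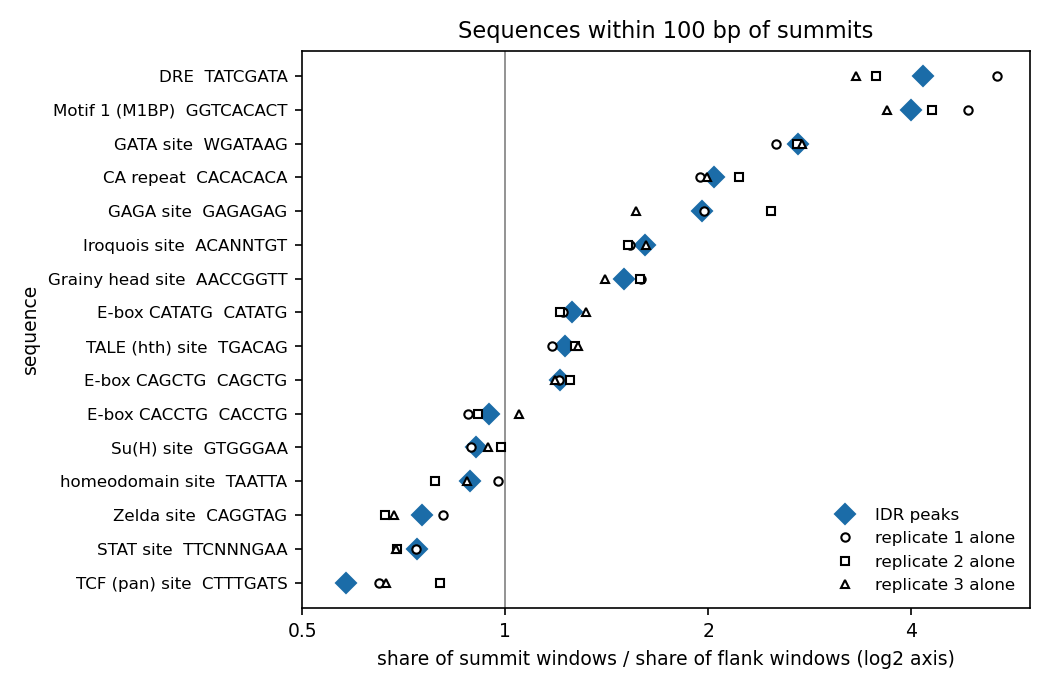
Ratio of the share of summit windows to the share of flanking windows that hold each of 16 sequences, on a log2 axis; filled diamonds are IDR peaks and open symbols the single replicates. The Iroquois sequence lies at 1.61 and the GATA sequence at 2.72.

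Promoters of 3494 of 13945 genes (25.1%) had a summit within 1000 bp, and 24.4% ± 3.24 in the replicate lists (SD, n = 3). Among the developmental lists, 2 passed the Fisher test, those of the EGFR and Dpp pathways. In the EGFR pathway 10 of 17 genes were bound (58.8%, log2 odds ratio 2.07, SE 0.69, Fisher's exact test, adjusted p = 0.0188). They included the feedback inhibitor gene sty (peak 73, signal 1328), the ETS factor genes pnt (peak 745) and aop (peak 1840) and the ligand gene spi (peak 1342), whereas aos, which encodes a secreted inhibitor, and the adaptor gene drk were not bound. In the Dpp pathway 9 of 16 genes were bound (56.2%, log2 odds ratio 1.92, SE 0.71, Fisher's exact test, adjusted p = 0.0363), among them shn (peak 81, signal 1265), the receptor gene sax (peak 2176), the repressor gene brk (peak 2437) and cv-2 (peak 2458); the ligand genes dpp and gbb were not bound. Neither list stood apart from random lists matched on locus length, which gave 6.44 and 5.45 genes on average (permutation test over matched lists, adjusted p = 0.51 for each). With any 1 replicate left out, neither call held in both remaining replicate lists, and the share in the replicate lists was 54.9% ± 12.2 for EGFR and 47.9% ± 9.55 for Dpp (SD, n = 3).

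The 3 control lists that passed the test differed most from other genes. Of the cytosolic ribosomal protein genes, 72 of 92 were bound (78.3%, replicates 78.6% ± 5.36, SD, n = 3), against 16.5 in matched lists. The log2 odds ratio was 3.43 (SE 0.36, Fisher's exact test, adjusted p = 2.3e-25). Against matched lists the adjusted p was 0.0016 (permutation test over matched lists), with the unadjusted p at its floor of 0.0002. The strongest were RpS27 (peak 21), RpL7 (peak 46), RpL14 (peak 77) and RpS4 (peak 85), and RpL10 and RpL10Aa were not bound. A list of 30 other highly transcribed genes, drawn up after this was seen, was bound at 66.7%, without a comparison with matched lists. Of 179 odorant, gustatory and ionotropic receptor genes, 5 were bound (2.79%, log2 odds ratio -3.43, SE 0.63, exact test, adjusted p = 4.49e-15), namely Or88a, Ir60e, Gr64a, Gr32a and Gr63a, the last named after its value was seen; Gr10a and Gr10b were not. Of 115 cuticle protein genes, 2 were bound (1.74%, log2 odds ratio -3.94, SE 0.92, exact test, adjusted p = 3.88e-11), Cpr73D and Cpr65Av, while Ccp84Aa and Ccp84Ab were not. Both also lay below matched lists, which gave 39.0 and 19.7 genes. Of 48 proteasome genes 9 were bound (18.8%), which did not pass the test (exact test, adjusted p = 0.672).

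The other 18 lists did not pass the Fisher test. The Wingless list passed it by locus (log2 odds ratio 2.60), and the tracheal (3.41), Iroquois complex (4.45) and appendage lists (1.83) by nearest TSS. The genes named here were chosen after their values were seen. In the Iroquois complex, mirr and caup were bound in the IDR list and ara was not; replicate 1 alone had all 3 bound. Among signalling lists, 7 of 21 Notch, 8 of 18 Wingless, 4 of 11 Hedgehog and 3 of 8 JAK/STAT list members were bound. The Notch list as fixed also held Notum, an inhibitor of Wingless signalling, which was not bound. The bound Hedgehog genes were ci (peak 110), rdx, ptc and disp, and the JAK/STAT genes Stat92E (peak 321), Socs36E and dome. None of the 8 Hox genes was bound in the IDR list (exact test, adjusted p = 0.458). Matched lists gave 3.32 genes on average (permutation test over matched lists, adjusted p = 0.157). By locus 5 of the 8 had a summit, which did not set them apart from other genes (log2 odds ratio 0.53, exact test, adjusted p = 0.88). Among patterning lists the counts were 3 of 10 gap and terminal genes (nanos, hb and cad), 4 of 16 pair-rule and segment polarity genes (hry, bowl, sob and inv), 5 of 11 dorsal ectoderm genes (ush, pnr, rho, C15 and tup) and 6 of 15 appendage genes, with Dll at peak 289. They were 2 of 7 spalt, T-box and related genes (org-1 and salm) and 3 of 13 retinal determination genes (eyg, dac and hth). Among neural lists, 3 of 19 proneural and neuroblast genes (emc, brat and esg), 4 of 16 genes of the nerve cord columns and temporal series (oc, SoxN, svp and hth) and 4 of 16 axon guidance genes (robo2, unc-5, Sema2a and Sema1a) were bound. The counts were 3 of 14 for mesoderm and muscle genes (sls, Mef2 and tin), 6 of 10 for tracheal genes (exact test, adjusted p = 0.0796) and 8 of 19 for adhesion and planar polarity genes, with Toll-7 at peak 106. Not all of these peaks recurred in each replicate. For example, the relaxed list of replicate 1 had no region at the peaks of hb and rho. That of replicate 2 had none at the peaks of pnr and esg.

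**Figure D3:**
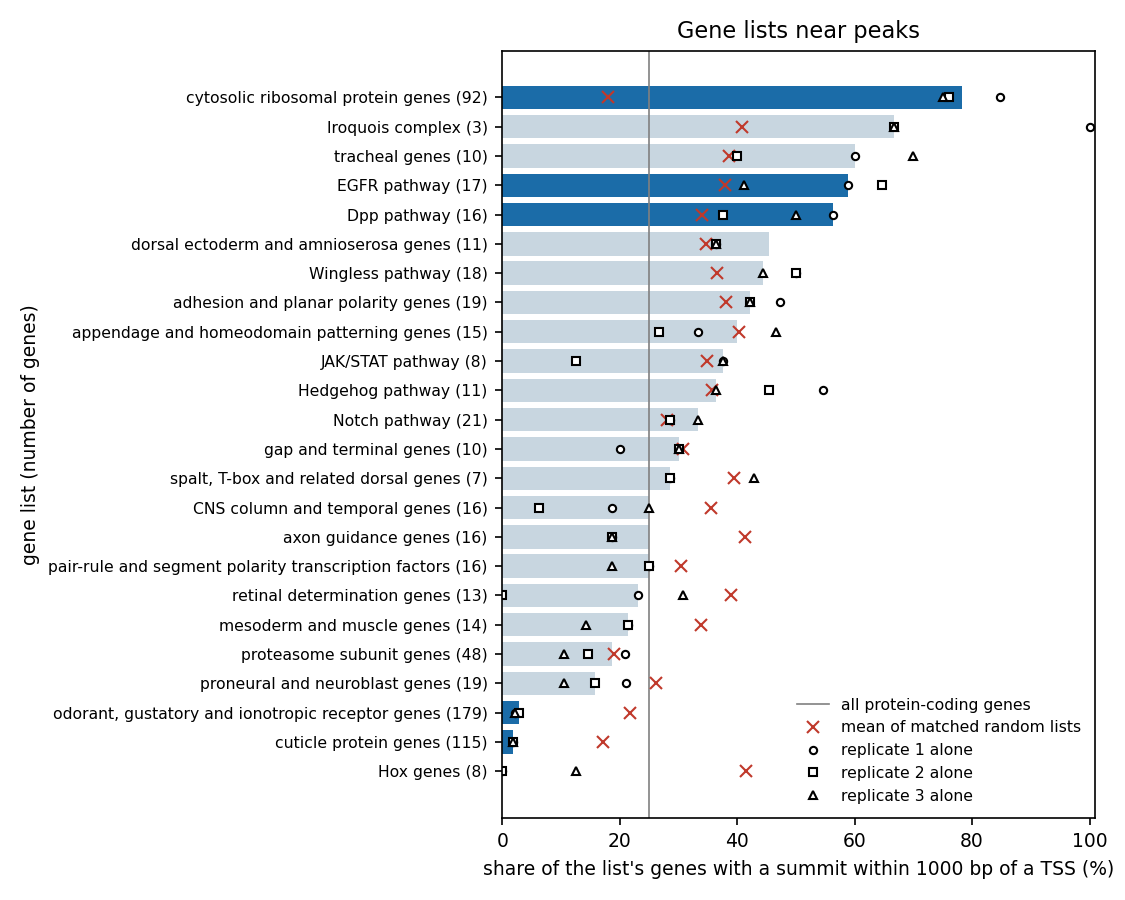
Share (%) of each list's genes with an IDR summit within 1000 bp of a TSS; dark bars passed the Fisher test, crosses give the mean of matched random lists, open symbols single replicates, and the line all genes (25.1%). Ribosomal protein genes stood at 78.3% and cuticle protein genes at 1.74%.

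The locus that encodes the tagged protein was densely occupied, and unevenly. The window from 20 kb before ara to 20 kb after mirr (3L, 12560672 to 12730249) held 40 IDR summits, whereas windows of the same length held 7.90 on average (percentile 99.98 of 13289 overlapping windows; 39.3 ± 9.45 summits in the replicate lists, SD, n = 3). Of the 40 summits, 30 had mirr as the nearest gene, 6 had caup and 1 had ara. The strongest lay 42 bp from the TSS of mirr, in a peak from 12692291 to 12693889 with a signal of 3588 and ranks 10, 1 and 4 in replicates 1, 2 and 3. The next was intergenic, 37376 bp from that TSS (12655840 to 12656941, signal 2558, ranks 30, 15 and 5). Peak 35, 3124 bp from the TSS, and peak 40, 40308 bp from it, were also intergenic. At caup, peak 3987 lay 92 bp from the TSS with a signal of 254.0, and ara had no promoter peak and 1 intronic summit, in peak 3734. The Iroquois sequence lay within 100 bp of 6 of the 40 summits and of none of the 4 strongest. The 50-kb window with the most summits on the chromosome arms lay here as well (3L, 12650001 to 12700000), with 26 summits against a mean of 2.32 and mirr as its 1 gene with a TSS. A transgene that carries the mirr region can add copies of it, and its ends were not used here.

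**Figure D4:**
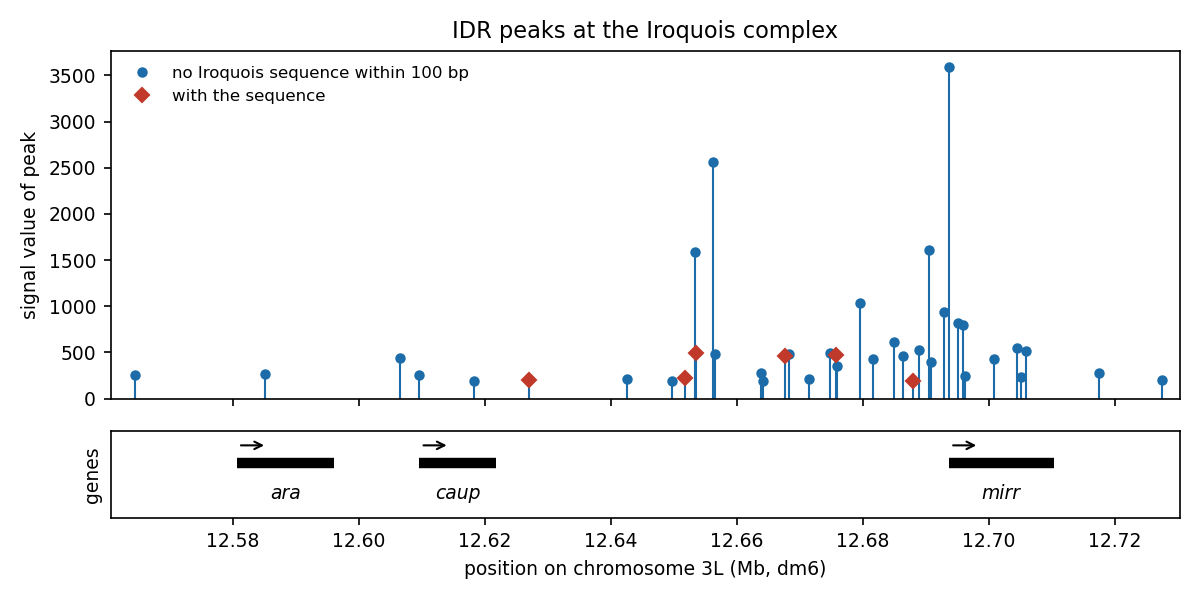
Signal of each IDR peak (vertical axis, the authors' scale) against its position on chromosome 3L (Mb) at the Iroquois complex, with gene bodies and their direction below; red diamonds hold the Iroquois sequence within 100 bp. The 2 highest peaks, at 3588 and 2558, lie at the mirr promoter and 37376 bp from it.

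Of the other dense windows of 50 kb, 3 held 22, 22 and 20 summits. On 2L, from 12000001, the window included the TSSs of CG18788, CG6766, CG6770, CG6785, Hacd1, PLCXD, Plzf, Rh5, Tom70, Wdr81 and dmGlut. On 3R, from 16200001, the window held those of CG31287, CG6126, mtSSB and the transcriptional coregulator gene tara, and from 14010001 those of CG3061, CG9922, Cyp6d5, rdx and foxo, the effector of insulin signalling. The replicate lists held 17.0 ± 1.00, 20.7 ± 0.577 and 19.0 ± 2.00 summits there (SD, n = 3).

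Within the IDR list, no difference in placement between stronger and weaker peaks was detected. The share of promoter summits was 45.4%, 45.5%, 45.4% and 43.5% from the strongest to the weakest of 4 bins of equal size, and the share with the Iroquois sequence 13.3%, 13.6%, 12.8% and 13.9%. The mean rank of promoter peaks was 3072 against 3125 for others (two-sided permutation test, p = 0.246, adjusted p = 0.491), and 3106 with the Iroquois sequence against 3100 without it (p = 0.927, adjusted p = 0.927). Fewer promoter summits than other summits held the sequence, 11.9% against 14.6% (log2 odds ratio -0.34, SE 0.11, Fisher's exact test, p = 0.00213).

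Chromosome X carried 37.7 peaks per Mb, against 50.1 on 2L, 52.2 on 2R, 46.4 on 3L and 46.8 on 3R. Relative to relaxed-only regions, X had fewer peaks (log2 odds ratio -0.27, SE 0.06, Fisher's exact test, adjusted p = 2.63e-05) and 2R more (log2 odds ratio 0.21, SE 0.05, adjusted p = 0.000138). The embryos were of mixed sex, so the copy number of X could differ from that of the other arms, which was not examined here. In the replicate lists the call for X did not hold without replicate 1 or without replicate 2, with mean log2 odds ratios of -0.20 and -0.16. Chromosome 4 held 11 peaks and 12 relaxed-only regions; its log2 odds ratio of 1.75 (SE 0.59, exact test, adjusted p = 0.00899) became -2.52 against arm length, and in the replicate lists its call was lost with any 1 replicate left out. The remaining arms did not pass the test (exact test, adjusted p = 0.0835 for 2L, 0.847 for 3L and 0.134 for 3R).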

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

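Of 495 recomputed values, 389 kept their direction and side of the threshold or moved by less than the spread, 30 lost and 18 gained the threshold, 15 moved and 43 changed sign; the cause was not tested unless given. The Iroquois and GATA sequences, the promoter share and the ribosomal, receptor and cuticle lists kept direction and threshold under all alternatives run on them (log2 odds ratios 0.44 to 0.85, 1.18 to 1.88 and 1.38 to 2.66 for the first 3). Keeping 1 summit per merged region, chosen after seeing the data, changed no call. The share of peaks in all replicates was 33.2% with 50% reciprocal overlap, 48.4% with summits within 100 bp, 93.8% with whole relaxed lists, 86.9% for the 3100 strongest peaks and 65.1% to 68.7% with 1 replicate left out, where fewer lists had to overlap. Log2 odds ratios, unless stated, follow. With a TSS window of 250 bp the 5' UTR passed at 0.43 and the 3' UTR at -0.32; against genome bases they passed at 0.47 and -1.69, and the intron did not at -0.010. Leaving out a replicate gave -0.48 to -0.31 for the 3' UTR, which passed without replicate 2. Against relaxed-only summits the sign changed for TALE (-0.35), Zelda (0.14), homeodomain (0.14), CA repeat (-0.046), CACCTG (0.14), STAT (0.037) and Grainy head (-0.039) sequences; among peaks over 1000 bp from a TSS it changed for Motif 1 (-0.59) and CACCTG (0.089), and with 250-bp windows for the homeodomain sequence (0.015). Calls were lost for TALE with 250-bp windows (0.097) and the 3100 strongest peaks (0.27), and gained with 250-bp windows for Zelda (-0.35), CACCTG (-0.21) and Grainy head (0.49), without replicate 1 for Zelda (-0.57) and against relaxed-only summits for Su(H) (-0.47). The EGFR call was lost with a 5000-bp window (1.81), the 3100 strongest peaks (1.77) and each replicate left out (1.57 to 2.23). The Dpp call was lost by locus (0.94), with 500-bp (1.56) and 5000-bp windows (1.29), the strongest peaks (1.53) and each replicate left out (1.40 to 1.74). The number of lists bound more often was 3, and became 6 by nearest TSS and 1 with a 5000-bp window, with the strongest peaks and without each replicate. By nearest TSS the Iroquois (4.45), tracheal (3.41), appendage (1.83) and proteasome lists (-1.66) passed, and by locus the Wingless list (2.60). Among the other lists, signs changed by locus for Hox (0.53), gap (-1.22), pair-rule (-1.19), mesoderm (0.67) and spalt lists (-0.48); by nearest TSS for Hox (1.65), retinal (0.57) and mesoderm (1.65); with 500 bp for mesoderm (0.18) and axon guidance (-0.047); with 5000 bp for JAK/STAT (-0.43), gap (-0.88), pair-rule (-0.84), mesoderm (0.61), spalt (-0.92) and axon guidance (-1.25); and with the strongest peaks for the nerve cord (-2.45) and mesoderm (0.27). Leaving out replicates gave -0.15 to 0.10 for pair-rule, -1.09 to -0.15 for nerve cord, -1.60 to 0.23 for retinal and -0.38 to -0.16 for axon guidance genes. The percentile of the Iroquois window was 99.72 with margins of 50 kb and 99.81 to 99.90 with 1 replicate left out. Rank differences passed no test. That of the Iroquois sequence was 6.08 ranks in the main setting and 173 ranks with 50-bp windows (permutation test, adjusted p = 0.0916). Its sign changed with 250 bp (-25.7 ranks). Against arm length 2L passed (0.14), 3L (0.0028), 3R (0.019) and chromosome 4 (-2.52) changed sign; with the strongest peaks 2L (0.21) and 3R (-0.14) passed and chromosome 4 did not (1.69). Leaving out replicates gave 0.028 to 0.060 for 3L, -0.38 to -0.16 for X and 0.74 to 1.10 for chromosome 4, whose call was lost each time; that of X was lost without replicate 1 or 2. Read depth is unknown, so its effect on the number of peaks could not be examined. No paired analysis was possible because the samples formed 1 group.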

Other observations

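The tests of broadly expressed genes, of highly transcribed genes, of neighbouring promoters and of transgene copies were chosen after the results they bear on were seen, as were the search of all 7-base sequences and the shares of GATA sequences by promoter class, signal bin and Iroquois sequence; the design names no biological explanation to test against these, since the samples form 1 group.

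Among 8146 sequences of 7 bases, the 5 with the highest odds at summits against flanks all held GATAA: CGATAAG (9.97% of summits, ratio 3.33), GATAAGA (12.4%, 3.13), TGATAAG (13.8%, 3.05), CTGATAA (11.7%, 2.98) and GATAAGC (9.21%, 2.74), read on either strand. The first that did not hold GATA was AGTGTTG, at place 17 (5.64%, 2.38). Several before it held GATA without GATAA, such as CGATAGT (place 6) and TCGATAC (place 16). The promoter element DRE (TATCGATA) holds GATA as well, so these need not be sequences of GATA factors. In all, 1240 sequences were more and 1420 less frequent at summits (Fisher's exact test, Benjamini-Hochberg adjustment). WGATAAG itself was more common at summits away from promoters (23.2%) than at promoters (16.3%, log2 odds ratio -0.63, SE 0.09, Fisher's exact test, p = 1.07e-11). It was found at 22.7%, 21.4%, 19.4% and 17.0% of summits from the strongest to the weakest of 4 bins of equal size. Its share was 18.5% at summits with the Iroquois sequence and 20.3% at those without it. That difference did not pass the test (log2 odds ratio -0.17, SE 0.14, exact test, p = 0.227).

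The GATA sequence may mark sites shared with GATA factors, a hypothesis that these lists cannot decide. Base composition would have placed other orders of its letters beside it; WGATAAG ranked 1 of 60 orders with a ratio of 2.72, and the next order reached 1.54. Promoter peaks do not account for it, since the ratio was 3.08 among the 2722 peaks over 1000 bp from a TSS. Accessible chromatin that many factors occupy stays open, as no accessibility data or unrelated factor was used here.

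The bound ribosomal protein promoters may reflect high transcription, which can raise recovered DNA in ChIP whatever the antibody. Of 30 other highly transcribed genes, listed from general knowledge without expression values, 66.7% were bound. Already known to lie at the strongest peaks were 2 of them, and without these it was 18 of 28 (64.3%). Unlike the ribosomal protein list, this list was not set against lists matched on locus length. How much of its share follows locus length is therefore unknown. Of 48 proteasome genes, 18.8% were bound, against 25.1% of all genes and 19.0% in lists matched on locus length. They were taken by symbol, without expression values. Their share argues against broad expression alone only if they are broadly expressed, which was not checked. Of 73 mitochondrial ribosomal protein genes, 24 were bound (32.9%, Fisher's exact test, adjusted p = 0.136). Peaks of neighbouring promoters were argued against, since 93.1% of the 72 bound ribosomal protein genes had their strongest summit within 100 bp of their own TSS, at a median of 18 bp. An untagged control would separate recovery from binding and was not used here.

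The cluster of peaks at mirr may reflect extra copies brought by the transgene or regulation of the gene by its own product, a hypothesis that was not tested here. Summits split within overlapping peaks did not make up the cluster. With 1 summit per merged region the Iroquois window kept 34 summits, at percentile 99.94. Only overlapping peaks were merged, so a broader region called as separate neighbouring peaks was not tested. With all signals in the window halved, as a simple stand-in for a doubling of copies, 23 of 40 summits stayed above the lowest IDR signal, at percentile 96.46. The signal has no stated scale, so halving it need not match a change in copies, and no conclusion was drawn. Copy number and binding cannot be told apart there, because the ends of the transgene and an input track were not used here. The lists were called against a control alignment, and whether that already offset extra copies was not tested.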
